A study of Poeciliopsis prolifica with 16 samples.

How the data were processed

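Reads per gene were deposited for 16 RNA-seq libraries of Poeciliopsis prolifica from lines A and B, comprising 12 juvenile whole-fish libraries, 2 embryo libraries and 2 placenta libraries. The authors deposited raw read counts per gene, whole numbers not scaled to depth, in a table of 28632 genes. Per the submitters' processing notes, the tools named are FastQC, Trimmomatic 0.36, TopHat2 2.1.1 and bedtools. The counting program, strand setting, treatment of reads with several matches, genome build and annotation are not given in the sources used here. Per the labels' protocols, juvenile libraries were made with both unstranded and strand-specific kits, but which library used which kit is not given in the sources used here. Reads of near-identical copies and of overlapping or antisense genes are therefore uncertain. The protocol describes the embryo libraries as made with another kit and sequenced on another instrument with longer reads, and places the embryos at stage 45 where the titles say 40. It does not mention the placenta libraries.

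Samples were grouped by tissue and line from their titles. The protocol gives 3 fish per line while there are 6 juvenile libraries per line, so juvenile counts were summed over libraries sharing a title token into 4 library sets, 2 per line. This holds as long as no fish spans tokens, which the labels do not say. The summed sets held 30083891 to 76209109 reads. Single libraries held 2982170 to 29932920 reads. Intervals and floors cover counting error only, and a floor of 3 counts per library was used where a group had no read.

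A gene counted as detected in a library at 10 or more reads. Differences were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were line B against line A in the juvenile sets, placenta against embryo in the 4 stage-40 libraries, embryo against the juvenile sets, and line B against line A over 8 samples with sample type as a covariate. Standard errors were obtained as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are CPM by library total. Alternatives were median-of-ratios scaling, DESeq2 1.42.0, no low-count filter, a 2-fold minimum, other replicate units including limma 3.58.1 with library sets as a random block, blocks, and leaving out each set or library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the interval of a ratio of reads was computed with scipy 1.17.1.

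Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The gene lists were fixed by symbol or product name. The reference table of assembly Auburn_PproV2 lists 29041 genes and none with an Ensembl identifier, so 0 of the 28632 identifiers matched a name and no list was tested. The rule then allows 2 identifiers that rose and 2 that fell per comparison, those with the largest change among genes past the threshold, at a mean of at least 10 CPM in the higher group and with no overlap of the groups. Fold bounds and pooled ratios with a sample left out were added after the data were seen.

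Embryo and placenta of a line share the line and the number in their titles, so they were taken as paired by label. The line A minus line B differences in embryo and placenta correlated across genes with a Pearson r of 0.209. The result with line as a block is given beside the unblocked result.

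The tests were tried on simulated counts drawn from the real means and library sizes and seeded sets of changed genes. The spread per gene was the one fitted to the real counts, and changed genes were seeded only among those at a mean of at least 1 CPM. In the placenta against embryo design, 0 of 70 genes changed 4-fold, 8 of 70 changed 16-fold and 53 of 60 changed 256-fold were called among 21261 genes. In the embryo against juvenile design these were 3 of 70, 51 of 70 and 60 of 60 among 25790 genes. The juvenile line design called 9 of 70, 64 of 70 and 60 of 60 among 26144 genes. The line design over all sample types called 4 of 70, 61 of 70 and 59 of 60 among 25700 genes. Unchanged genes called numbered 4, 6, 16 and 7 in the same order. In the real juvenile sets, 44 genes at an edgeR adjusted p under 0.1 did not pass 0.05. Their median absolute log2 changes were 6.55 (25 genes higher in line B) and 5.68 (19 genes lower). The simulated recovery is therefore no measure of which real line differences would be called.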

Results

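The series profiled gene expression in Poeciliopsis prolifica, the blackstripe livebearer, a small live-bearing fish whose females nourish their embryos through a placenta. According to its title, the series served the annotation of the species' genome, with an eye to how the placenta of these fishes evolved. RNA-seq reads per gene were deposited for 28632 genes in 16 libraries from 2 lines, line A and line B. Each line gave 6 libraries of whole juvenile fish, 1 library of embryos and 1 library of placenta, the latter pair titled as stage 40.

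The juvenile libraries fell into 4 sets that share a token in their titles, here called n3 and n6 in line A and n1 and n5 in line B. The protocol names 3 fish per line against 6 libraries, so the libraries cannot all be separate fish, and the reads were summed within each set before testing. No statement was found that ties sets or libraries to separate animals, so the p-values measure only the spread between these samples, which may in part be technical. Library totals ran from 2982170 reads in the line B n5 library 4 to 29932920 reads in the line A n6 library 1. Among the other juvenile libraries only the line A n6 library 4, with 3918921 reads, lay below 14654378 reads. The embryo libraries held 14758373 reads in line A and 24386758 reads in line B. The placenta libraries held 8647318 reads in line A and 13404689 reads in line B. Within a library set, log2 expression of the juvenile libraries correlated across genes at a Pearson r of 0.905 to 0.993, against 0.785 to 0.929 between the sets of a line (median 0.860) and 0.715 to 0.926 between lines (median 0.831). Between summed sets, r was 0.941 within line A and 0.915 within line B, against 0.866 to 0.951 between lines, with the highest for n3 and n5. Genes are not independent replicates in such correlations. No library pair of a set agreed within sampling noise, so none was treated as a repeat deposit.

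**Figure D1:**
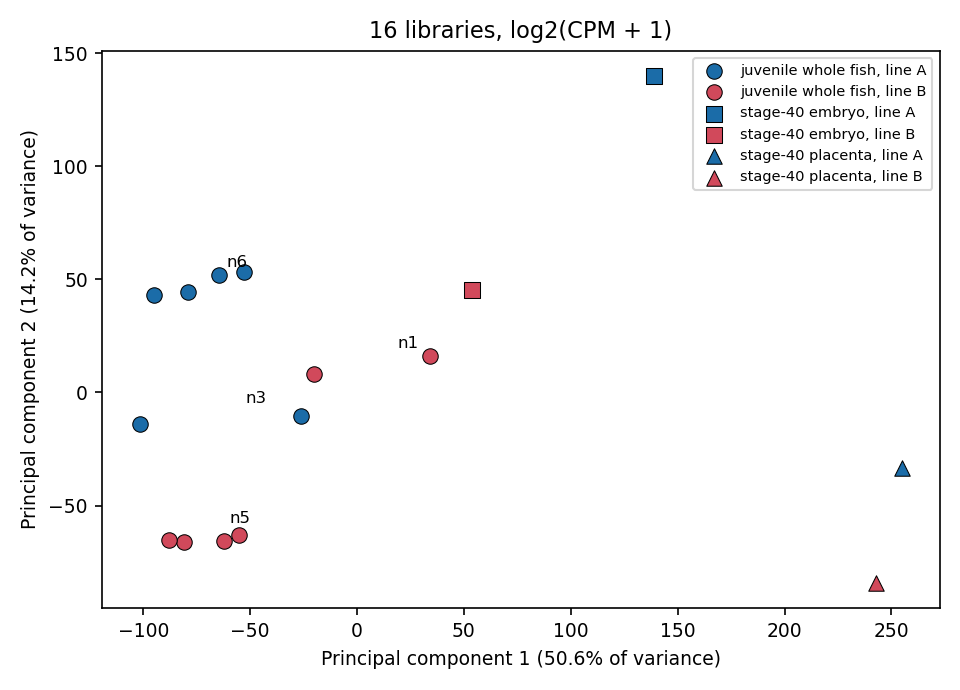
Principal component scores of the 16 libraries, computed on log2(CPM + 1), with the share of variance on each axis; circles are juvenile fish, squares embryos and triangles placentas, blue for line A and red for line B. The placenta libraries lie farthest to the right, the embryo libraries lie between them and most juvenile libraries, and the line B n1 juvenile libraries lie closest to the line B embryo library.

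The first readout of an annotation series is which annotated genes carry reads. At 10 or more reads, 26549 genes, 92.7% of the table, were detected in at least 1 library, and 11730 genes were detected in all 16. Libraries of whole juvenile fish detected the most genes on average, 23118 ± 1817 (SD, n = 12), which was 80.7% of the table. Embryo libraries detected 20654 genes in line A and 22887 genes in line B. Placenta libraries detected 15622 genes in line A and 17019 genes in line B, a mean of 57.0% of the table. The order of the means held with each library thinned to 2982170 reads, at 18171 ± 778 genes in juveniles (SD, n = 12), 15705 ± 1849 in embryos (SD, n = 2) and 11535 ± 75.7 in placentas (SD, n = 2). Single juvenile and embryo libraries overlapped. The line B n1 library 2 detected 22564 genes, or 16398 after thinning, fewer than the line B embryo library with 22887, or 17012 after thinning. Embryo libraries differed from juvenile ones in kit, read length and sequencer, and the protocol does not describe the placenta libraries. Sample type and library preparation therefore cannot be told apart in this order.

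Genes detected in embryo or placenta but in no juvenile library were few, while genes that reached 10 reads in embryo but not in placenta were many. Both embryo libraries and neither placenta library detected 3012 genes, and 1709 of these were also detected in all 12 juvenile libraries. Both placenta libraries and neither embryo library detected 74 genes. These sets were counted at 10 reads without thinning. Each placenta library was shallower than both embryo libraries, so depth may account for part of this contrast. Only 37 genes were detected in both embryo libraries and in no juvenile library, and 18 in both placenta libraries and in no juvenile library, with 7 genes in both lists. A gene at 10 reads in any of the 12 juvenile libraries was left off these lists, which keeps them short. All 12 juvenile libraries, but no embryo or placenta library, detected 105 genes. At the other end, 334 genes had no read in any library. The 100 most abundant genes took 53.0% of the reads in the line A placenta and 47.2% in the line B placenta. The same measure was 36.6% and 36.7% in the embryo libraries and 27.1% to 46.7% in the juvenile libraries. For the 10 most abundant genes there was no such order, at 18.1% and 23.8% in the placentas of lines A and B and 10.2% to 23.8% in the juvenile libraries.

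**Figure D2:**
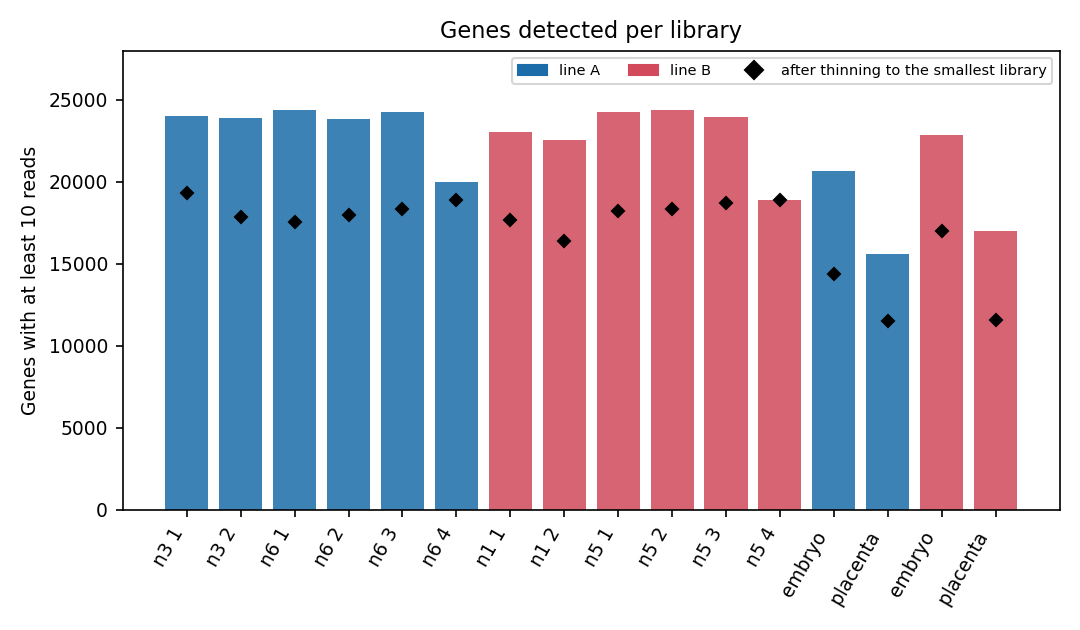
Genes with at least 10 reads in each of the 16 libraries (bars, number of genes; blue line A, red line B), with the number after thinning to 2982170 reads as black diamonds. The placenta bars reach 15622 and 17019 genes and are the lowest bars, and their diamonds, at 11481 and 11588 genes, are the lowest diamonds.

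The identifiers of the table carry several prefixes, and no table used here pairs any of the 28632 identifiers with a gene name, so genes are described by level and sample type. The most common prefix, ENSPPRG without a suffix, covered 26339 genes and 88.6% of all reads, and 92.4% of these genes were detected in at least 1 library. The 1769 genes with the prefix ENSXMAG held 8.65% of the reads, and 96.8% of them were detected. Detection in both placenta libraries was 46.8% for the first class and 54.4% for the second. A prefix of poePro_, which every identifier in the table has, is left out here.

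Placenta was compared with embryo of the same title stage to ask which genes separate the exchange tissue from the embryo it serves, with the 2 lines as replicates. Of 21261 genes tested, 538 were lower and 38 were higher in placenta, against 1293 lower and 390 higher with line as a block. The 538 lower genes were well expressed in embryos, with a median of 48.8 CPM (reads scaled to the library total) in line A and 58.6 CPM in line B, and close to absent from placenta, at 0.231 and 0.298 CPM. They were no embryo-only group, since 522 of them reached 1 CPM in every juvenile set, and 97 had no read in either placenta library. The 38 higher genes had a median of 129 CPM in the line A placenta and 76.1 CPM in the line B placenta, against 2.81 and 5.11 CPM in the embryos. Of these 38 genes, 31 also reached 1 CPM in every juvenile set. The protocol does not describe the placenta libraries, so any difference in their preparation cannot be told apart from tissue.

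The largest called rises were uneven between the lines. ENSXMAG00000022556 reached 21250 CPM in the line A placenta and 57.1 CPM in the line B placenta, against 9.62 and 5.37 CPM in the embryos of lines A and B (log2 fold change 11.16, SE 2.65, edgeR adjusted p = 0.0484). Its level in the juvenile sets was 818 to 1286 CPM. ENSPPRG00000007627 was as uneven, at 4752 CPM in the line A placenta, 17.6 CPM in the line B placenta, and 1.97 and 1.44 CPM in the embryos (log2 fold change 11.16, SE 2.44, edgeR adjusted p = 0.0367). Both folds rested on the line A placenta, without which the log2 fold changes were 3.71 and 4.18, and with line as a block they were 8.05 and 8.21. Without either embryo library neither gene passed, nor did they with the 4 libraries thinned to the smallest (edgeR adjusted p = 0.0821 and 0.0661), where 7 genes were called higher and 240 lower. Among the falls, ENSPPRG00000003600 had no read in either placenta library and 103 and 56.6 CPM in the embryos of lines A and B, at least 280.1-fold lower at a floor of 3 reads per library (edgeR adjusted p = 0.0275). ENSPPRG00000044250 also had no placenta read, with 125 CPM in the line A embryos and 9.55 CPM in the line B embryos, at least 235-fold lower (edgeR adjusted p = 0.0285). Without the line A embryo library that bound was 33.5-fold and the call was lost (edgeR adjusted p = 0.333, against 0.00141 to 0.0795 with another library left out), and without the line B embryo library neither fall passed.

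Across the 21261 tested genes, the placenta minus embryo difference in log2(CPM + 1) correlated between lines with a Pearson r of 0.526. In both lines, 2263 genes were at least 4-fold lower in placenta and 236 at least 4-fold higher on that scale. It uses library totals without the TMM factors of the test, and it places placenta lower. For example, ENSPPRG00000000163 (-0.63 in line A, -0.70 in line B) and ENSPPRG00000000418 (-0.79 and -0.67) were on the higher side in the test. The 4-fold cuts therefore favour lower genes, and these numbers overstate their excess relative to the test. A gene at least 4-fold higher in line A and 4-fold lower in line B was seen 61 times, and the opposite 28 times. The counts of called genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With line as a block it called 1683 genes, 1293 lower and 390 higher, which included all 576. The count fell to 0 without the line B embryo library and to 129 without the line A embryo library, and it rose to 1972 without the line A placenta (713 higher, 1259 lower) and 1820 without the line B placenta (358 higher, 1462 lower). With DESeq2 2701 genes passed, 74.3% of them lower against 93.4% in the edgeR test.

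**Figure D3:**
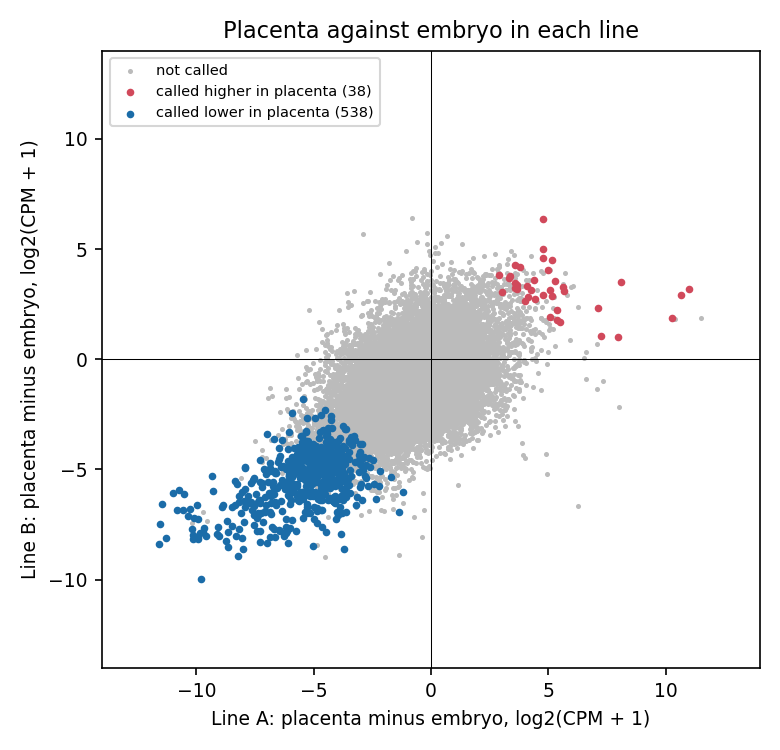
Placenta minus embryo difference in log2(CPM + 1) for each tested gene, line A on the horizontal axis and line B on the vertical axis; blue points are the 538 genes called lower in placenta, red points the 38 called higher, and grey points the other genes tested. The lower genes form a broad cloud at the lower left, and the higher genes include several with a far larger difference in line A than in line B. The differences use library totals without the TMM factors of the test, which places genes lower on both axes than in the test.

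Embryos were compared with whole juvenile fish to describe the change in expression between these stages. Of 25790 genes tested, 690 were higher and 685 lower in embryos, a balance that moved to 1281 higher and 922 lower with median-of-ratios scaling and to 454 higher and 793 lower with line as a covariate. The 690 higher genes had a median of 42.0 CPM in the line A embryos and 30.2 CPM in the line B embryos, against 8.24 CPM in juveniles, and 595 of them reached 1 CPM in every juvenile set. The 685 lower genes had a median of 0.881 and 1.56 CPM in the embryos against 21.0 CPM in juveniles, and 59 had no read in either embryo library. In placenta the lower genes were also scarce, at a median of 0.925 CPM in line A and 0.821 CPM in line B.

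The 2 largest called rises in embryos were more abundant still in placenta. ENSPPRG00000012416 had 220 CPM in the line A embryos, 3708 CPM in the line B embryos, 6029 and 56030 CPM in the placentas of lines A and B, and a mean of 0.102 ± 0.0333 CPM in juveniles (SD, n = 4 sets; log2 fold change 14.22, SE 1.2, edgeR adjusted p = 0.0131). ENSPPRG00000052215 had 92.3 and 431 CPM in the embryos, 697 and 7774 CPM in the placentas, and 0.0298 ± 0.0274 CPM in juveniles (SD, n = 4 sets; log2 fold change 13.15, SE 0.95, edgeR adjusted p = 0.0126). Without the line B embryos these log2 fold changes were 11.44 and 12.01, and without set n3 neither gene passed. Placental genes nearly silent in juveniles stood in embryos at a median of 2.04% of their placental level in line A (15 genes) and 6.06% in line B (21 genes). No value excluded placental RNA in the embryo library of either line, which bears on the embryo levels of both genes. Of the falls, ENSPPRG00000003607 averaged 304 ± 170 CPM in juveniles (SD, n = 4 sets) with no read in either embryo library, at least 1864-fold lower in embryos at the floor of 3 reads per library (edgeR adjusted p = 0.0132). ENSPPRG00000041743 had no embryo read and was uneven among juveniles, at 3.40 CPM in n3, 4.65 in n1, 56.5 in n6 and 65.7 in n5, at least 199.5-fold lower in embryos (edgeR adjusted p = 0.0498) and at least 132-fold without n5. The call on the first fall was lost without n3 or the line A embryos, and that on the second without n3, n6, n5 or either embryo library.

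Per the labels' protocols, embryo libraries differed from juvenile libraries in kit, read length and sequencer, so stage and library batch cannot be told apart in these 1375 calls. The count fell to 0 without set n3, 20 without n6, 35 without n5 and 5 without the line A embryos, rose to 2103 without n1 and 6928 without the line B embryos, and was 7142 with DESeq2.

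Between juveniles of the 2 lines, no gene of 26144 passed edgeR's quasi-likelihood test over the 4 library sets. The lowest adjusted p was 0.0597. At an unadjusted p under 0.05 there were 2420 genes, 692 higher and 1728 lower in line B, and DESeq2 called 1169. By chance 1307 would be expected, but only if the p-values reflect the spread between separate fish. The labels do not establish that, so the excess alone is no evidence of a line difference. Without set n6 the 2420 fell to 921. The 44 genes at an adjusted p under 0.1 were close to present-or-absent. Their 25 members with higher values in line B had medians of 0.111 and 0.173 CPM in the line A sets n3 and n6, and 10.8 and 10.6 CPM in the line B sets n1 and n5. Their 19 members with lower values in line B had medians of 30.9 and 18.9 CPM in the line A sets and 0.233 and 0.354 CPM in the line B sets. Leaving out n5 gave 12 calls, n1 gave 6, and single libraries gave at most 29, without the line B n1 library 1. With the 12 libraries as separate replicates the count was 3762. That fit takes every library as a separate fish, which the 3 fish per line of the protocol do not allow. With the form of the title, shared by n3 and n1 and by n6 and n5, as a block over the 4 sets, 576 genes passed, 103 higher and 473 lower in line B.

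Across juvenile, embryo and placenta samples together, 23 genes were higher and 18 lower in line B than in line A, of 25700 tested. The 23 higher genes were nearly silent in line A, with medians of 0.0835 and 0.0665 CPM in the juvenile sets n3 and n6, 0.0678 CPM in the embryos and 0 in the placenta. In line B their medians were 3.76 and 9.21 CPM in n1 and n5, 8.73 CPM in the embryos and 7.68 CPM in the placenta. The 18 lower genes had medians of 8.71, 9.56, 19.0 and 14.1 CPM in n3, n6, embryos and placenta of line A, and of 0.283, 0.276, 0.615 and 0.261 CPM in n1, n5, embryos and placenta of line B. In 39 of these 41 genes the 4 line A samples did not overlap the 4 line B samples. The same was true of 2.43% of all tested genes. Chance would give 2.86% only if the 8 samples were interchangeable. They are not, since they differ in sample type, so the 2.43% cannot be judged against that share.

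ENSPPRG00000048024 averaged 35.9 ± 23.1 CPM in line B (SD, n = 4) and had 9 reads in all of line A (log2 fold change 8.91, SE 0.75, edgeR adjusted p = 0.00403). ENSPPRG00000001960 averaged 57.8 ± 33.5 CPM in line B (SD, n = 4) and had 25 reads in line A (log2 fold change 8.54, SE 0.64, edgeR adjusted p = 0.00403). In the other direction, ENSPPRG00000046463 had no read in line B and 0.640, 0.811, 5.08 and 79.7 CPM in n3, n6, embryos and placenta of line A, at least 177-fold lower in line B on the means at a floor of 3 reads per library (edgeR adjusted p = 0.0292). Without the line A placenta that bound was 17.9-fold and the call was lost. ENSPPRG00000019980 had 3 reads in line B and 1032 in line A, a ratio of pooled, depth-scaled reads of 368 (95% interval 126 to 1789, counting error only; edgeR adjusted p = 0.0306), or 222 without the line A embryos. Embryo and placenta of one line may come from the same animals, so these p-values may be too small. The count was 0 without either embryo library, so none of the 4 named genes passed there. With sample type as a covariate, a lone embryo library says nothing about line, so each of these fits dropped all embryo evidence on line. The log2 fold change of ENSPPRG00000048024 was 8.74 without the line A embryos and 8.74 without the line B embryos. The count was 5 without n3, 2 without n6 and 21 without n5, and DESeq2 called 729 genes. Of the named genes, ENSPPRG00000046463 was also lost without n3 or n6, ENSPPRG00000019980 without n3, n6 or n5, and ENSPPRG00000048024 without n6.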

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

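All tests of single libraries here used a rule fixed in advance, while the tests of separate loss of transcripts in each placenta library, and of the placenta comparison on thinned libraries, were chosen after the results were seen. Of 34 tests for a library far from the others, 4 stood out, where chance alone gives about 1 in 20. That rate need not hold here, since the flagged gene levels lay near 0 and the flagged counts of genes came from the shallowest libraries. The line A n6 library 4 detected 20002 genes, against 23832 to 24387 in the other line A juvenile libraries, and it held 3918921 reads. The line B n5 library 4 detected 18883 genes, against 22564 to 24354 in the other line B juvenile libraries, and it held 2982170 reads. ENSPPRG00000052215, a gene higher in embryos, stood at 0.0964 CPM in the line A n6 library 2 and at 0 in the other 5 line A juvenile libraries. ENSPPRG00000048024, a gene higher in line B, stood at 0.510 CPM in the line A n6 library 4, against at most 0.131 CPM in the other line A juvenile libraries.

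More genes were called lower than higher in placenta, 538 against 38, but 1259 against 713 (63.8% lower) without the line A placenta and 1462 against 358 without the line B placenta. Unequal depth as the cause is argued against by the 247 genes called after thinning the 4 libraries to the smallest, 97.2% of which were lower. Scaling cannot be told apart, since median-of-ratios scaling (92.0% lower) moved the median log2 change of all genes only from -0.06 to -0.07. DESeq2, no low-count filter and line as a block, none of which changes the scaling alone, gave 74.3%, 72.1% and 76.8% lower. Genes at 5 to 20 CPM in one placenta library had no read in the other 3.41 times (line B) and 9.57 times (line A) as often as in the embryo pair, so lost transcripts may add to the excess, although real differences between the placentas of the lines would give such zeros too. Even with all such zeros read as losses, separate losses as the whole cause would leave about 6.55 genes unread in both placenta libraries among all those tested, whereas 86 of the lower genes were unread in both and at 5 CPM or more in both embryo libraries. A loss that strikes the same genes in both libraries and a difference between the tissues themselves, which was not tested, stay open.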

How the results depend on the processing

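The thinned placenta comparison was added after the data were seen; the other alternatives were planned. Against 0 edgeR calls between juvenile lines (2420 genes at an unadjusted p under 0.05), DESeq2 gave 1169, no low-count filter 26, 12 separate libraries 3762, these with title form as a covariate 4712, limma with sets as a random block 915, libraries with rep in the title 11325 and those without it 1553. The edgeR fits on separate libraries treated libraries of a set as replicates. Those with and without rep compared a single set per line (n6 with n5, n3 with n1), so they cannot separate line from set. Numbers in juvenile titles were not taken as pairs, since 1 of the 6 same-numbered pairs' deviations from their line means correlated at -0.0848; the others gave 0.112 to 0.511, and within sets the rep numbers correlated best with their own number (0.605 to 0.702), a hint from the data only. As a replicate block the number gave 5027 calls, and title form as a block over the 4 sets gave 576. For placenta against embryo (576), DESeq2 gave 2701, no filter 2100 (72.1% lower), line as a block 1683 and thinning 247, and the median log2 change of all genes was -0.19 with DESeq2 against -0.06. For embryo against juvenile (1375), median-of-ratios scaling gave 2203 and DESeq2 7142; line as a covariate gave 1247, 63.6% lower against 49.8%. For lines over all types (41), DESeq2 gave 729 (54.9% lower against 43.9%), no filter 65 and 16 separate libraries 3383. Leaving out 1 set or library gave 0 to 29 calls for juvenile lines, 0 to 1972 for placenta, 0 to 6928 for embryo and 0 to 56 (without the line B placenta) for lines over all types; the cause was not tested. Detected genes averaged 26537.9, 25519.5 and 21721 in juveniles, embryos and placentas at 1 read, 18170.5, 15704.5 and 11534.5 after thinning, and 20011.5 in embryos at 1 CPM, with the order of sample types kept; without either library the embryo mean was 20654 to 22887 and the placenta mean 15622 to 17019. Named genes kept direction in all 124 alternatives and fell short of the threshold in 34, of which 31 left out a set or library. The gene-list alternatives were not run because no identifier matched a name, and the planned direction check of juvenile line calls in embryo and placenta has no value because the unblocked edgeR test over the 4 sets called none. Thinning to the smallest library lowered the mean of detected genes in every sample type, so these counts are limited by depth. Depth did not set the order of the sample-type means.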

Other observations

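The tests in this part on genes at an adjusted p under 0.1 or an unadjusted p under 0.05, on other divisions of the juvenile library sets, on genes read in one line only and on placental genes in embryos were chosen after the results were seen. Genes abundant in one placenta library alone were found in both lines. In the line A placenta 39 genes reached 100 CPM and 20 times the level of both embryo libraries, and 27 of them also stood 20 times above the line B placenta. Of those 27 genes, 9 reached 10 CPM in every juvenile set. In the line B placenta the numbers were 29, 16 and 5.

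Genes abundant in placenta and nearly silent in juveniles were read in embryos at a low share of their placental level. In line A, 15 genes at 100 CPM or more in placenta, and at under 1% of that level in every juvenile set, stood in embryos at a median of 2.04% of the placental level (quartiles 0.932% and 4.15%). In line B, 21 such genes stood at a median of 6.06% (quartiles 3.64% and 9.35%). Of the genes at 1000 CPM or more in placenta, 10 of 155 in line A and 0 of 151 in line B stood in embryos below 1% of their placental level. The lowest of these shares were 0.0212% in line A and 3.25% in line B. In line A, 7 genes stood below 0.511%, far under the line A median. This argues against even carry-over of all RNA of that placenta library at a share near the median. The 7 were picked by level in that library alone. They include ENSXMAG00000022556 and ENSPPRG00000007627, at 57.1 and 17.6 CPM in the line B placenta. Such genes need not be placental, so carry-over of placental RNA alone stays open. In line B, 0 genes stood below the matching limit of 1.51%, so carry-over, or expression in the embryos themselves, may lie behind the line B levels. An earlier form of this test, on fewer silent genes, did not decide the question.

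Line differences over all sample types rested on few genes, and the other divisions of the samples that were tried gave none. The 41 calls between lines were matched by none of the other divisions of the 8 samples into 4 and 4. Of 34 divisions, 1, the real one, gave as many, and the highest of the others gave 0. Only 12 divisions are balanced over sample types like the real one, too few for a share under 0.05. The count was 0 without either embryo library, where the remaining embryo library says nothing about line. Of the 44 genes at an edgeR adjusted p under 0.1 between juvenile lines, 95.3% of those with a direction kept it in embryos and 89.7% in placenta. These libraries were not used to choose them, and the shares lay at least 35.9 percentage points above matched genes. For these genes, that goes with a line difference carried through these sample types. Among the 41 calls are 11 of their 25 genes higher in line B and 8 of their 19 lower, so the 2 lists are not separate evidence. At 1 CPM or more in every sample of one line and under 0.1 CPM in every sample of the other, 8 genes were read in one line only, against at most 0 in the 11 other divisions balanced over sample types. Of these 8 genes 12.5% were read in line A only and 87.5% in line B only, while juvenile genes at an unadjusted p under 0.05 ran the other way, with 1728 lower and 692 higher in line B, so poorer matching of either line's reads to the genome, whose line is not given in the sources used here, cannot be told apart from genes that a line lacks or does not express.

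With 12 separate libraries, 3762 genes passed between juvenile lines, and none with 4 summed sets by edgeR, where 2420 had an unadjusted p under 0.05 and DESeq2 called 1169. Grouping n3 with n5 against n6 with n1, which mixes the lines, gave 3507 calls on the 12 libraries, while grouping n3 with n1 against n6 with n5 gave 4, so sharing of RNA within sets cannot be told apart from a line difference. The direction of these 3762 genes in embryos and placenta lay at least 4.35 percentage points above that of matched genes (61.4% against 56.9%, and 58.4% against 54.1%), below the 10 points set in advance for a line difference carried by these tissues. Both shares nonetheless lay above the highest of 100 draws of matched genes, 59.4% and 56.3%, and for the 2420 genes at an unadjusted p under 0.05 the excess was 13.2 and 7.87 points.

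Among the 4 libraries of n6 and of n5, those numbered 1 and 2 differed least, with a chi-square per degree of freedom of 13.9 and 8.86, followed by those numbered 3 and 4, with 19.5 and 15.9. The other pairs of these sets ran from 31.6 to 47.6.

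Sets differed in how near they stood to embryos. Across genes, log2(CPM + 1) of the line B set n1 correlated with the line B embryos at a Pearson r of 0.894 and shared 71 of the 100 most abundant genes with them, while n5 of the same line stood at 0.843 and shared 57. In line A the sets n3 and n6 both stood at 0.739 against the line A embryos. Every set stood nearer the line B embryo library, n3 and n6 at 0.833 and 0.811, so values against different embryo libraries cannot be compared between sets. Against the line A embryos, n1 stood at 0.816 and n5 at 0.693.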
